A study of Mus musculus with 15 samples.

How the data were processed

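The 15 mouse libraries were poly(A) RNA-seq of CD4 T cells. Per the labels' protocols, naive CD4 T cells negative for CD25 with high CD62L and low CD44 were sorted from spleen and lymph node and stimulated with plate-bound anti-CD3 and anti-CD28. TH17 cultures received TGFβ at 2.5 ng/ml, IL-6, IL-1β and IL-23. Treg cultures received TGFβ, at 0.5 ng/ml or another stated dose, and IL-2. Both received antibodies against IFNγ and IL-4. Srci1 was added 24 h after plating, at a concentration that the labels used here do not give, and cells were harvested on day 5. The knockout mice carried floxed Stat3 alleles and a Cre driven by Cd4. RNA was extracted with TRIzol and libraries were made with the NEBNext Ultra II kit.

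The deposited table held TPM values for 55421 Ensembl gene IDs in 15 columns, with 2 decimals, and every column was matched to a library by its name. TPM is a transcript's share of all transcripts after correction for length, scaled to a fixed total. Per the submitters' processing notes, STAR 2.7.9a, RSEM 1.3.3 and the GRCm38 build were used, with no role or option given. The annotation release, the strand setting and any filter are not given in the sources used here, so overlapping and antisense genes may share reads. Each library sums to about the same total, so the depth per library is unknown and neither a counting interval nor a detection floor was computed. Symbols were taken for 55154 IDs from a table of gene names, and 106 symbols belonged to more than 1 ID. Coordinates are 1-based on GRCm38 from GENCODE release M21, which held a record for 55240 of the IDs with the version ignored.

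Groups were taken from the labels, with 3 libraries in each of 5 groups. The 6 comparisons were Srci1 against DMSO in TH17 cells, STAT3 knockout against wild type in TH17 cells, Srci1 against DMSO in Treg cells, Treg against TH17 cells in DMSO, the Srci1 effect in TH17 minus that in Treg cells, and the Srci1 effect minus the knockout effect in TH17 cells. The last is the direct difference of Srci1 and knockout libraries. limma 3.58.1 in R 4.3.3 was run on log2(TPM + 1) with a trend of the variance on the mean, for 12800 genes with at least 1 TPM in at least 3 libraries. All 15 libraries entered a single model of 5 group means with 10 residual degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05.

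Before the data were examined, 24 gene lists with 346 entries were fixed, all of which matched the table, along with the tests, the alternatives and the rule for named genes. The lists were the TH17, Treg, TH1, TH2 and TFH programs, STAT3 pathway and targets, naive and memory T cell genes, TCR-induced genes, the IL-2 and STAT5, type I interferon, TGF-beta, amino acid stress (ATF4), p53 and unfolded protein and heat shock responses, cell cycle, glycolysis and hypoxia, cholesterol synthesis, Src family kinases and regulators, mitochondrially encoded genes, and markers of B cells, myeloid and dendritic cells, CD8 T and NK cells, gamma delta T cells and red blood cells. Some genes stood in more than 1 list, such as Socs3 and Pim1 in the STAT3 and IL-2 lists, Tnfrsf4 in the Treg and TCR-induced lists, and Itgae in the Treg and TGF-beta lists. Lists were tested with camera in limma at a preset inter-gene correlation of 0.01, and again with an estimated correlation. List medians are given relative to the median of all tested genes unless stated otherwise.

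The named genes were a fixed set (Stat3, Src, Lck, Fyn, Il17a, Il17f, Il23r, Foxp3, Il2ra and Socs3) in every comparison, the called genes of largest fold change in each direction, and up to 4 members of each described list with the smallest adjusted p. The largest-change genes had no overlap between the libraries of the groups compared and a group mean of at least 5 TPM. They left out unnamed gene models, pseudogenes, mitochondrially encoded genes and immune receptor segments. The largest-change genes numbered 6 in each direction, and 4 for the last 2 comparisons. Some genes chosen by this rule are not reported here. Which lists are described gene by gene in each comparison was chosen after the list results were seen.

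The alternatives were a pseudocount of 0.1, no filter on low values (23425 genes), a stricter filter of 5 TPM (10041 genes), median-of-ratios scaling, quantile normalization, only the compared groups in the model, array weights, the replicate number as a block, each library left out in turn, and the estimated inter-gene correlation. Added after the data were seen were a rescaling without 230 ribosomal protein and mitochondrial genes, and the list tests without DMSO TH17 replicate 3. Those 230 genes were matched by symbol (Rpl or Rps with a digit, or mt-), which can take in pseudogenes and other genes whose symbols start alike. The ribosomal protein share of TPM used the same Rpl and Rps match. The overlap of calls between comparisons that share DMSO libraries was set beside 100 simulations of unchanged groups.

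The fits were tested on simulated data with 12800 genes of which 200 were changed, against 1821 to 6366 genes called in the real comparisons. The shares below thus hold for few changed genes and may differ where more genes change. At a log2 change of 1, 83.6% of changed genes were called for Srci1 in TH17 cells, 77.6% for the knockout, 76.1% for Srci1 in Treg cells, 79.1% for Treg against TH17 cells, 53.7% for the difference between cell types and 77.6% for Srci1 minus knockout. At a log2 change of 0.5 the same shares were 41.8, 37.3, 40.3, 38.8, 11.9 and 37.3%. Of all simulated calls, 2.9 to 7% were of unchanged genes. Simulated lists of 15 genes shifted by 0.5 reached an unadjusted camera p under 0.05 in 20 of 20 draws in each comparison. Unshifted lists did so in 0 to 3 of 20. Real lists were called at an adjusted p, which is stricter. Simulated genes were drawn independently, so these draws cannot show whether the preset inter-gene correlation suits the real lists. With an estimated correlation fewer real lists were called in every comparison, for example 3 against 14 for Treg against TH17 cells. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3.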

Results

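The transcriptomes of mouse CD4 T cells cultured under TH17 or Treg conditions were measured in 15 poly(A) RNA-seq libraries, 3 in each of 5 groups. TH17 cells, a helper lineage known for secreting IL-17, were grown with TGFβ, IL-6, IL-1β and IL-23. Treg cells, a lineage defined by the transcription factor FOXP3, were grown with TGFβ and IL-2. The protocols give TGFβ at 2.5 ng/ml for TH17 cultures and at 0.5 ng/ml, or another stated dose, for Treg cultures. Comparisons between the cell types thus also hold differences in cytokines and TGFβ dose. TH17 cultures received DMSO or Srci1, a compound known here only by that name, or came from mice lacking STAT3 in T cells and received DMSO. Treg cultures received DMSO or Srci1. The series concerns T cell receptor signalling and STAT3 phosphorylation in TH17 differentiation, and the groups set the compound beside loss of STAT3. Values below are mean TPM ± SD with n = 3 libraries per group, and fold changes on the log2 scale are of TPM + 1, which understates changes of low genes. Sequencing depth is unknown, because TPM sums to about the same total in every library. List counts are of genes that passed the test over all genes, and for the lists described the counts adjusted over the list alone were the same except where given.

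Libraries of a group correlated at r = 0.977 to 0.986 across the 12800 tested genes, which are not independent replicates, and libraries of different groups at 0.902 to 0.97. The first principal component held 38.8% of the variance and the second 22.4%. Ribosomal protein transcripts made up 28.4 ± 2% of TPM in DMSO TH17 libraries, 22.1 ± 0.6% with Srci1 and 28.7 ± 1.2% in the STAT3 knockout. In Treg libraries that share was 25 ± 0.2% with DMSO and 20.9 ± 0.5% with Srci1. The labels do not say that replicates came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical.

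**Figure D1:**
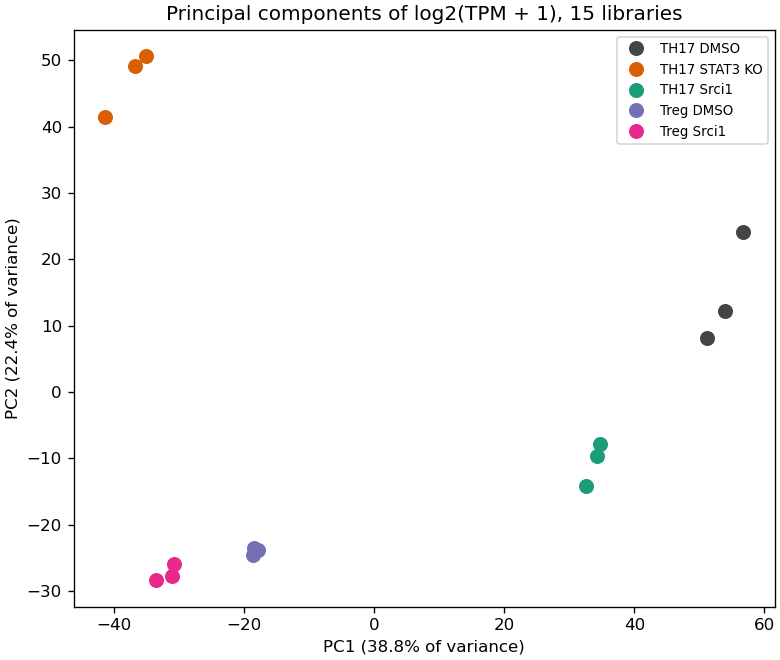
First and second principal components of log2(TPM + 1) for the 15 libraries, with each point a library coloured by group. The components held 38.8% and 22.4% of the variance, and the 3 libraries of each group lie beside each other.

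Stat3, on chromosome 11 from 100885098 to 100939540 on the minus strand of GRCm38 (ENSMUSG00000004040.16), was measured first as a check of the knockout labels. It was 34.2 ± 3.9 TPM in the knockout against 120.8 ± 18.3 TPM in wild-type TH17 cells, 3.53-fold lower (limma adjusted p = 3.75e-09). The knockout libraries held 33.5, 38.4 and 30.7 TPM and the wild-type DMSO libraries 129.7, 132.9 and 99.8 TPM. Srci1-treated TH17 libraries held 158.4, 152.2 and 160.9 TPM, DMSO Treg libraries 129.6, 133.7 and 139.9 TPM, and Srci1-treated Treg libraries 76.1, 75.2 and 78.3 TPM. A gene-level TPM can include transcript from which only some exons were removed.

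In TH17 cells, the signature TH17 cytokine transcripts fell with Srci1 and the Treg factor Foxp3 rose. Il17a (chromosome 1, 20730905 to 20734496, plus strand), which encodes IL-17A, fell from 1338 ± 51.5 to 40.4 ± 3.31 TPM, 33.2-fold (limma adjusted p = 8.08e-12). Il17f, which encodes IL-17F (chromosome 1, 20777146 to 20790617, minus strand), fell from 2551 ± 111 to 531.4 ± 18.1 TPM, 4.8-fold (limma adjusted p = 7.64e-08). Foxp3 (chromosome X, 7573644 to 7595245, plus strand) rose from 11.7 ± 2.15 to 203.6 ± 8.37 TPM, 17.4-fold (limma adjusted p = 1.17e-11). Transcripts of cholesterol synthesis rose together, while transcripts induced by the T cell receptor fell.

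Of 20 TH17 program genes, 12 fell, 5 rose and 3 did not pass the test, with a list median of -0.78 on the log2 scale relative to the median of all genes (camera adjusted p = 4.45e-08). The chemokine gene Ccl20 fell from 136.9 ± 7.26 to 33.2 ± 3.59 TPM, and the cytokine gene Il21 from 205.3 ± 35.5 to 54.5 ± 6.46 TPM. Il23r, the IL-23 receptor gene (chromosome 6, 67422932 to 67491855, minus strand), was 3.87 ± 1.06 against 7.29 ± 2.86 TPM (limma adjusted p = 0.0232). That call ended without DMSO TH17 replicate 1 (adjusted p = 0.0958), DMSO TH17 replicate 2 (0.0797) or Srci1 TH17 replicate 2 (0.0991), and with a pseudocount of 0.1 (0.169) or only the compared groups in the fit (0.133).

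Of 20 TCR-induced genes, a list of immediate-early and activation genes, 13 fell, 1 rose and 6 did not pass (relative median -0.76, camera adjusted p = 1.7e-12). The nuclear receptor gene Nr4a1 fell from 196.8 ± 4.58 to 74.2 ± 3.35 TPM, Egr3 from 19.8 ± 2.37 to 5.62 ± 0.39 TPM and Spry1 from 19.6 ± 1.76 to 9.47 ± 0.58 TPM. Glycolysis and hypoxia genes fell in 11 of 18 cases, 17 under median-of-ratios scaling, and rose in 0 (relative median -0.46, camera adjusted p = 5.33e-11). Examples were the oxygen-sensing hydroxylase gene Egln3 (369.8 ± 22.4 to 162.8 ± 0.77 TPM), Bnip3 (194.3 ± 5.33 to 108.1 ± 6.43 TPM) and the glucose transporter gene Slc2a1 (146.1 ± 6.88 to 102.1 ± 4.57 TPM).

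All 20 cholesterol synthesis genes rose, by a relative median of 0.89 (camera adjusted p = 8.98e-14). Hmgcs1, an early enzyme of the pathway, rose from 55.3 ± 6.31 to 161.5 ± 21.7 TPM, Mvd from 50.4 ± 1.15 to 126.5 ± 6.45 TPM and Nsdhl from 20.6 ± 1.24 to 54.7 ± 2.62 TPM. All 20 cell cycle genes rose as well (relative median 0.67, camera adjusted p = 1.7e-12; adjusted p = 0.0552 with an estimated correlation), and 17 of them rose under median-of-ratios scaling. The ribonucleotide reductase gene Rrm2 rose from 93.9 ± 6.18 to 244.7 ± 9.64 TPM and Birc5 from 110.3 ± 10.5 to 249 ± 4.03 TPM. Of 12 naive and memory T cell genes, 8 rose and 1 fell, 9 and 1 adjusted over the list alone (camera adjusted p = 0.00838; adjusted p = 0.267 with an estimated correlation). Klf2, a transcription factor gene, rose from 25.2 ± 4.11 to 78.6 ± 5.2 TPM.

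The Treg program as a list was not called (11 of 19 genes rose, 3 fell; camera adjusted p = 0.132), though it was without a filter on low values, after median-of-ratios scaling or after quantile normalization (camera adjusted p = 0.0117, 0.0143 and 0.0304). Besides Foxp3, the integrin gene Itgae rose from 1.06 ± 0.25 to 8.06 ± 0.76 TPM and Gpr83 from 9.62 ± 1.52 to 25.3 ± 0.87 TPM, while Tnfrsf4, also a TCR-induced gene, fell from 812.9 ± 51.4 to 503.9 ± 5.24 TPM. The STAT3 pathway and targets list was not called either (7 of 15 rose, 2 fell, and 5 each under median-of-ratios scaling; camera adjusted p = 0.575). Socs3 (chromosome 11, 117966079 to 117970047, minus strand), a feedback inhibitor of cytokine signalling, rose from 82.5 ± 5.27 to 154.8 ± 3.58 TPM, and the cytokine receptor gene Il6st from 5.95 ± 2.24 to 23.9 ± 1.08 TPM. Pim1 rose from 392.2 ± 36 to 548.7 ± 15.5 TPM and Fos from 5.84 ± 0.72 to 18.7 ± 1.56 TPM. Il2ra (chromosome 2, 11642807 to 11693193, plus strand), the IL-2 receptor alpha chain gene, rose from 692.4 ± 109 to 1208 ± 70.7 TPM. Among the kinase genes, Src (chromosome 2, 157418444 to 157471862, plus strand) was 2.37 ± 0.31 against 1 ± 0.35 TPM (limma adjusted p = 0.0024). Lck (chromosome 4, 129548344 to 129573641, minus strand) was 403.9 ± 9.97 against 402.1 ± 19.3 TPM (limma adjusted p = 0.917). Fyn (chromosome 10, 39368855 to 39565381, plus strand) was 100.9 ± 2.66 against 89.7 ± 8.97 TPM, with an adjusted p from limma of 0.0486 and a direction that turned under median-of-ratios scaling (log2 fold change -0.095) and quantile normalization (-0.030). The Fyn call ended without DMSO TH17 replicate 3 (limma adjusted p = 0.182) or Srci1 TH17 replicate 1, 2 or 3 (0.0997, 0.0633 and 0.135). It also ended without a filter on low values (0.0617), with only the compared groups in the fit (0.175), with array weights (0.0628) and after rescaling without ribosomal protein and mitochondrial genes (0.451). Lck was lower with Srci1 under median-of-ratios scaling (log2 fold change -0.263, limma adjusted p = 0.00743) and after quantile normalization (-0.125, adjusted p = 0.0496). Stat3 itself rose from 120.8 ± 18.3 to 157.2 ± 4.49 TPM (limma adjusted p = 0.00731), a call that ended under median-of-ratios scaling (0.159) and with only the compared groups in the fit (0.0525).

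The largest rises by the naming rule, after Foxp3, were of Drc1, a dynein regulatory complex gene (0.23 ± 0.11 to 16.6 ± 1.7 TPM), the cytokine gene Il3 (0.84 ± 0.63 to 21.1 ± 4.14 TPM) and Actr3b (5.45 ± 1.02 to 70.3 ± 2.12 TPM). Myo6, which encodes myosin VI, rose from 18.4 ± 2.73 to 200.4 ± 3.5 TPM and the transcription factor gene Gata1 from 2.22 ± 0.99 to 30 ± 7.73 TPM. Among the largest falls, after Il17a, were those of Serpinf1 (175.9 ± 1.63 to 20.1 ± 2.04 TPM), the homeobox gene Vax2 (7.8 ± 1.99 to 0.18 ± 0.16 TPM), Ly6c1 (172.8 ± 4.98 to 26.5 ± 6.52 TPM) and Lgals7 (20.9 ± 5.35 to 2.81 ± 1.02 TPM). Reads can be shared between Ly6c1 and its near-identical neighbours, so that value is uncertain. Among B cell markers 2 of 6 measured genes rose, 0 fell (2 and 1 adjusted over the list alone) and the list was not called (camera adjusted p = 0.711). Ighm, the IgM heavy chain gene, rose from 113.6 ± 2.67 to 527.8 ± 18.1 TPM and Ighd from 0.87 ± 0.25 to 3.57 ± 0.66 TPM, beside Cd79b at 0.25 ± 0.11 TPM with DMSO and 0.5 ± 0.17 TPM with Srci1.

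Over the 12800 genes, 4324 were higher and 906 lower with Srci1 in TH17 cells (limma, 552 and 164 of them at least 2-fold), so that 82.7% of calls were higher. The median of all genes lay 0.213 above 0 on the log2 scale, and median-of-ratios scaling, which removes that shift, gave 2126 higher and 2112 lower genes (50.2% higher; 265 and 287 at least 2-fold), with 3032 calls kept in the same direction and 0 turned. The ribosomal protein share of 22.1 ± 0.6% with Srci1 against 28.4 ± 2% with DMSO moved with all these groups.

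**Figure D2:**
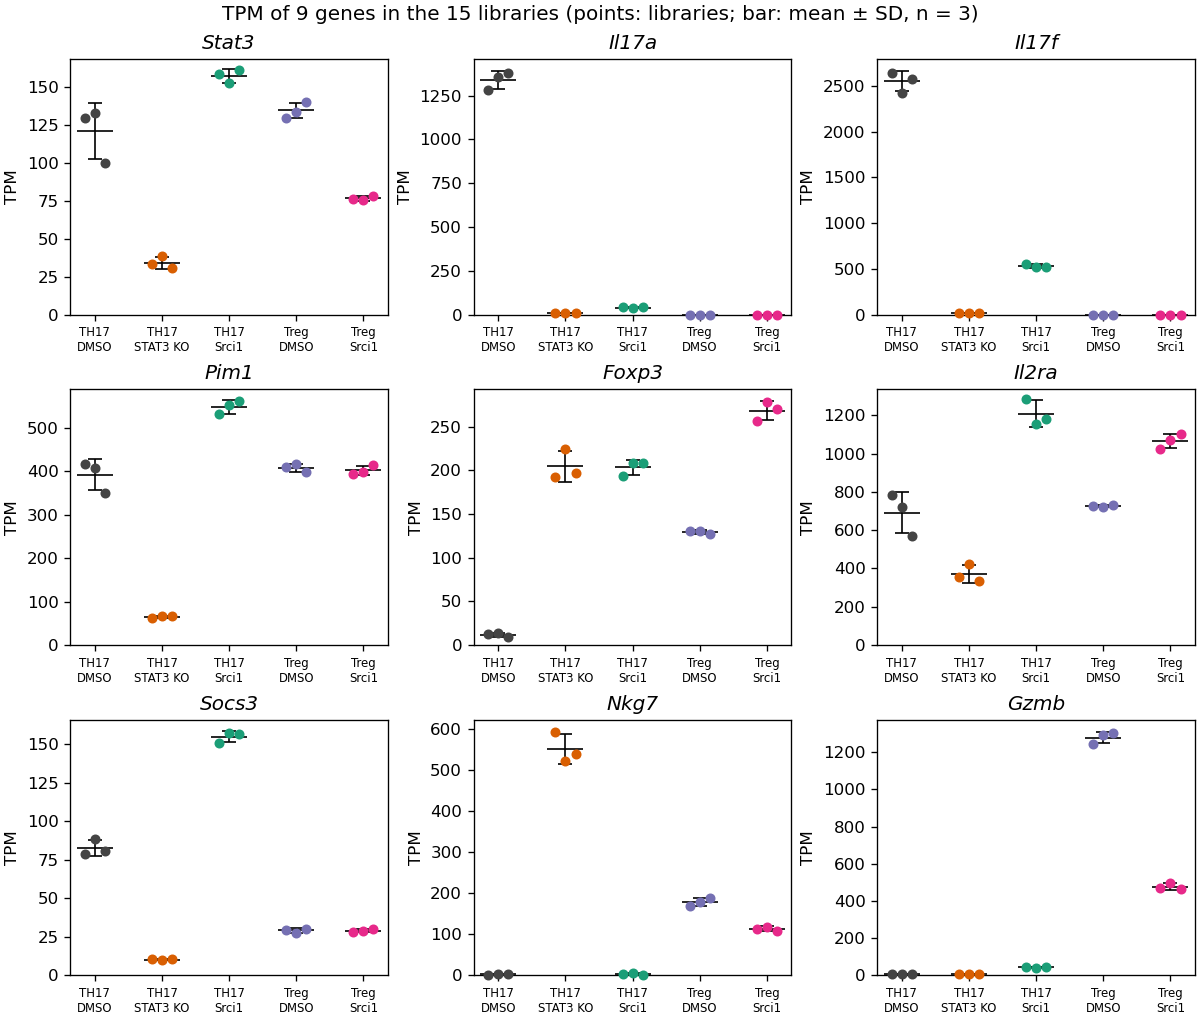
TPM of 9 genes in each of the 15 libraries, with points for libraries and bars for the group mean ± SD (n = 3), on linear axes from 0. Il17a was 1338 TPM in DMSO TH17 cells, 40.4 TPM with Srci1 and 10.2 TPM in the STAT3 knockout, while Socs3 was 82.5, 154.8 and 10.2 TPM in the same order.

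TH17 cultures lacking STAT3 held little TH17 cytokine transcript, and more Foxp3, Xcl1 and Nkg7 transcript than wild type. Il17a was 10.2 ± 1.45 TPM against 1338 ± 51.5 TPM in wild type, 131.6-fold lower (limma adjusted p = 2.8e-14), and Il17f was 19.1 ± 0.75 against 2551 ± 111 TPM. Il21 was listed at 0 in all 3 knockout libraries and at 205.3 ± 35.5 TPM in wild type. Foxp3 rose from 11.7 ± 2.15 to 204.6 ± 17.6 TPM, 17.5-fold (limma adjusted p = 9.26e-13). The chemokine gene Xcl1 rose from 3.55 ± 1.47 to 1584 ± 69.7 TPM and Nkg7, which encodes a cytotoxic granule protein, from 2.25 ± 0.45 to 551.2 ± 37.2 TPM.

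In the TH17 program 16 of 20 genes fell, 17 adjusted over the list alone, and 1 rose (relative median -2.18, camera adjusted p = 9.51e-14). Ltb4r1, a leukotriene B4 receptor gene, fell from 148.7 ± 7.51 to 0.1 ± 0.09 TPM and Il23r from 7.29 ± 2.86 to 0.06 ± 0.08 TPM. Of 15 STAT3 pathway and targets genes, 10 fell and 2 rose, with 11 falling adjusted over the list alone (relative median -1.56, camera adjusted p = 8.53e-07). Socs3 fell from 82.5 ± 5.27 to 10.2 ± 0.55 TPM, Pim1 from 392.2 ± 36 to 65.3 ± 2.1 TPM, Bcl3 from 135.4 ± 8.38 to 25.6 ± 3.08 TPM and Junb from 689.7 ± 84 to 223 ± 7.38 TPM. The IL-2 and STAT5 response, which shares Socs3 and Pim1 with that list, fell in 10 of 12 genes (relative median -1.18, camera adjusted p = 2.92e-08). Its members Cish (216.7 ± 13.5 to 64.3 ± 3.25 TPM), Osm (41.1 ± 1.72 to 12.1 ± 1.03 TPM) and Il2ra (692.4 ± 109 to 371.8 ± 46.8 TPM) fell.

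All 18 glycolysis and hypoxia genes fell in the knockout (relative median -1.84, camera adjusted p = 4.72e-22). Egln3 fell from 369.8 ± 22.4 to 10.1 ± 1.11 TPM, Slc2a1 from 146.1 ± 6.88 to 23.5 ± 0.74 TPM, Bnip3 from 194.3 ± 5.33 to 18.4 ± 2.1 TPM and the glycolytic enzyme gene Tpi1 from 1092 ± 18 to 337.4 ± 12.2 TPM. Unfolded protein and heat shock genes fell in 10 of 12 cases (relative median -0.88, camera adjusted p = 4.04e-07). Xbp1 went from 247.6 ± 3.24 to 69.9 ± 5.28 TPM and the chaperone gene Hspa5 from 366.6 ± 20 to 188.7 ± 13.9 TPM. Amino acid stress genes, which are targets of ATF4, fell in 10 of 15 cases and rose in 2 (relative median -0.71, camera adjusted p = 0.000235). Asns, the asparagine synthetase gene, fell from 42.6 ± 5.44 to 5.91 ± 0.98 TPM and Ddit4 from 219.9 ± 18 to 79.2 ± 3.68 TPM. Phgdh rose from 143.2 ± 5.61 to 248.1 ± 13.3 TPM. Cholesterol synthesis genes fell in 11 of 20 cases and rose in 2 (relative median -0.39, camera adjusted p = 0.0013; adjusted p = 0.195 with an estimated correlation). Fdps went from 242.4 ± 5.33 to 108.7 ± 13.8 TPM.

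The type I interferon response rose in 9 of 12 measured genes, 10 adjusted over the list alone, and fell in 1 (relative median 0.81, camera adjusted p = 0.00461). Gbp2 rose from 336.2 ± 27.1 to 769.3 ± 49.3 TPM and Irf9 from 19.1 ± 2.18 to 45.1 ± 3.02 TPM. The TH1 program was not called as a list (camera adjusted p = 0.0661), although 11 of its 17 genes rose and 5 fell. Tbx21, which encodes the TH1 factor T-bet, rose from 0.6 ± 0.13 to 21.9 ± 2.71 TPM, Ccl4 from 31.8 ± 3.42 to 230 ± 18.6 TPM and Cxcr3 from 3.8 ± 0.83 to 29.1 ± 1.38 TPM. Without a filter on low values, with a stricter filter or after median-of-ratios scaling the list was called (camera adjusted p = 0.015, 0.0248 and 0.0416). The Treg program rose in 10 and fell in 7 of 19 genes, 10 and 8 adjusted over the list alone, and was not called (camera adjusted p = 0.632). Its members Itgae (1.06 ± 0.25 to 124.2 ± 13.1 TPM), Tigit (7.67 ± 0.23 to 57.6 ± 2.09 TPM) and Penk (0.57 ± 0.1 to 33.3 ± 6.26 TPM) rose.

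Markers of other cell types moved in the knockout in both directions. B cell markers rose in 5 of 6 measured genes and fell in 1 (camera adjusted p = 0.0147; adjusted p = 0.0588 with an estimated correlation). Ighm went from 113.6 ± 2.67 to 710.8 ± 53.5 TPM, Ighd from 0.87 ± 0.25 to 27.5 ± 2.99 TPM and Cd79b from 0.25 ± 0.11 to 8.1 ± 0.92 TPM. Ebf1 fell from 2.6 ± 0.54 to 0.03 ± 0.04 TPM. Myeloid and dendritic cell markers rose in 5 and fell in 1 of 6 measured genes and were not called (camera adjusted p = 0.0714; 0.0416 after median-of-ratios scaling). Cd74 went from 38.4 ± 4.99 to 153.6 ± 14.2 TPM and H2-Ab1 from 71.5 ± 6.04 to 10.7 ± 2.01 TPM. CD8 T cell and NK cell markers rose in 3 and fell in 3 of 8 measured genes (camera adjusted p = 0.697). The receptor gene Klrd1 fell from 42.8 ± 1.88 to 1.27 ± 0.5 TPM. Cd8a was 4.74 ± 0.59 TPM against 0.02 ± 0.03 TPM and Prf1, the perforin gene, 6.28 ± 0.09 against 0.75 ± 0.29 TPM.

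The 6 largest rises also included the chemokine gene Ccl1 (0.2 ± 0.21 to 135.2 ± 4.35 TPM), Lcn10 (listed at 0 in the 3 wild-type DMSO libraries and at 72.2 ± 5.54 TPM in the knockout) and the interferon-inducible GTPase gene Iigp1 (0.33 ± 0.11 to 58.8 ± 12.2 TPM). The largest falls were of Timp1, a metalloproteinase inhibitor gene (431.9 ± 36.5 to 0.78 ± 0.48 TPM), the transglutaminase gene Tgm2 (210.8 ± 32.8 to 0.08 ± 0.06 TPM) and the uridine phosphorylase gene Upp1 (303 ± 20.7 to 1.45 ± 0.42 TPM), beside Il21, Ltb4r1 and Il17f. Src was 3.63 ± 0.27 against 1 ± 0.35 TPM, Lck 514.5 ± 4.78 against 402.1 ± 19.3 TPM and Fyn 136.7 ± 1.81 against 89.7 ± 8.97 TPM, all higher in the knockout (limma adjusted p = 2.73e-05, 1.8e-05 and 3.27e-06). In all, 3952 genes were higher and 2414 lower in the knockout (limma, 1128 and 775 at least 2-fold; 62.1% higher, all-gene median 0.129), against 3290 and 3245 (50.3% higher) under median-of-ratios scaling.

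In Treg cells, transcripts of TCR-induced, glycolysis, TH1 and interferon genes fell with Srci1 and Foxp3 rose. Foxp3 went from 129.7 ± 2.23 to 268.5 ± 11 TPM, 2.07-fold (limma adjusted p = 6.12e-06), and Il2ra from 726.7 ± 6.08 to 1066 ± 37.8 TPM. Stat3 fell from 134.4 ± 5.21 to 76.5 ± 1.58 TPM (limma adjusted p = 5.53e-05). Of 20 TCR-induced genes, 17 fell, 18 adjusted over the list alone, and 0 rose (relative median -0.84, camera adjusted p = 4.77e-17). Nr4a1 fell from 372.3 ± 10.2 to 131.9 ± 3.26 TPM, Tnfrsf9 from 1148 ± 19.5 to 389.2 ± 31.2 TPM and Egr1 from 76.6 ± 2.06 to 25.6 ± 1.21 TPM.

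All 18 glycolysis and hypoxia genes fell with Srci1 in Treg cells (relative median -1.08, camera adjusted p = 3.69e-28). Egln3 fell from 154.8 ± 1.63 to 15.6 ± 0.66 TPM and the lactate transporter gene Slc16a3 from 333.1 ± 18 to 75.2 ± 5.25 TPM. The TH1 program fell in 10 of 17 genes and rose in 1 (relative median -1.45, camera adjusted p = 9.69e-10). Gzmb went from 1279 ± 30.7 to 476.6 ± 18.9 TPM, Tbx21 from 45 ± 1.72 to 11.8 ± 1.46 TPM and Ccl3 from 239.1 ± 4.59 to 47 ± 9.32 TPM. Type I interferon genes fell in 10 of 12 cases, 11 with 1 rise adjusted over the list alone (relative median -1.02, camera adjusted p = 4.18e-08). Ifi27l2a fell from 1864 ± 69.6 to 979.4 ± 56.6 TPM. Amino acid stress genes fell in 13 of 15 cases (relative median -0.58, camera adjusted p = 6.84e-13), among them Asns (83.8 ± 2.3 to 24.7 ± 3.86 TPM) and Atf3 (25 ± 6.54 to 3.69 ± 1.62 TPM). TH2 genes fell in 5 of 10 cases and rose in 1, 6 and 1 adjusted over the list alone (camera adjusted p = 0.000489).

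Cholesterol synthesis genes rose in 14 of 20 cases, 16 adjusted over the list alone (relative median 0.43, camera adjusted p = 5.27e-07; adjusted p = 0.0717 with an estimated correlation). Mvd went from 42 ± 0.64 to 78.3 ± 0.67 TPM and Sqle from 60.5 ± 1.88 to 99 ± 0.86 TPM. The Treg program rose in 6 and fell in 7 of 19 genes, 7 and 8 adjusted over the list alone, and was not called (camera adjusted p = 0.131; 0.0485 with a stricter filter). Tigit fell from 101.7 ± 6.12 to 12 ± 1.49 TPM and Tnfrsf4 from 1114 ± 35.2 to 594.4 ± 17.4 TPM. Gpr83 rose from 19.9 ± 0.72 to 48.1 ± 0.93 TPM. Gamma delta T cell markers rose in 3 of 4 measured genes (relative median 1.76, camera adjusted p = 0.000749; 0.098 without a filter on low values). These were the receptor constant-region genes Tcrg-C4 (4.82 ± 0.56 to 25.6 ± 1.55 TPM), Tcrg-C2 (14 ± 2.5 to 49 ± 3.16 TPM) and Tcrg-C1 (7.11 ± 0.56 to 31.3 ± 2.82 TPM), which can share reads, whereas Trdc, the delta chain gene, was 0.52 ± 0.07 and 0.79 ± 0.26 TPM (limma adjusted p = 0.234).

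The other lists called in this comparison lost the call with an estimated correlation. These were the cell cycle (16 of 20 rose, 19 adjusted over the list alone and 12 under median-of-ratios scaling; adjusted p = 0.0717 with an estimated correlation), STAT3 pathway and targets (6 of 15 fell, 7 adjusted over the list alone, 2 rose; 0.0717), myeloid and dendritic cell markers (2 of 6 fell; 0.0717) and mitochondrially encoded genes (7 of 13 rose, 9 adjusted over the list alone; 0.109). The same held for the TH17 program (7 of 20 fell, 3 rose, 7 and 4 adjusted over the list alone; 0.224), the TFH program (4 of 10 fell, 5 adjusted over the list alone, 1 rose; 0.224), naive and memory T cell genes (9 of 12 rose, 2 fell; 0.224) and the TGF-beta response (7 of 12 rose, 8 adjusted over the list alone, 1 fell; 0.253). The TH17 and myeloid calls also ended after quantile normalization (camera adjusted p = 0.07 and 0.0733), and the myeloid call without a filter on low values (0.0937). Mitochondrially encoded transcripts held 3.54 ± 0.13% of TPM with DMSO and 4.97 ± 0.48% with Srci1.

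By the naming rule the largest rises in Treg cells were of Pdlim4 (0.9 ± 0.29 to 28 ± 1.03 TPM), Myl10 (1.71 ± 0.57 to 31.4 ± 1.83 TPM), Myo6 (17.4 ± 0.75 to 153.5 ± 29.1 TPM), the globin gene Hba-a1 (2.17 ± 1.1 to 20.8 ± 4.5 TPM), Ms4a6c (2.24 ± 1.13 to 12.3 ± 1.47 TPM) and Nrep (4.83 ± 0.92 to 22.8 ± 0.84 TPM). Hba-a1 shares its sequence with Hba-a2 and Ms4a6c belongs to a family of close copies, so both values are uncertain, and the red blood cell list was not called (1 of 3 measured genes rose, 2 adjusted over the list alone; camera adjusted p = 0.224). The largest falls were of the retinoic acid-binding protein gene Crabp2 (243.9 ± 8.1 to 19.5 ± 4.89 TPM), the osteopontin gene Spp1 (66.1 ± 3.38 to 5.41 ± 1.33 TPM), Upp1 (29.4 ± 3.53 to 2.07 ± 0.64 TPM), Egln3, the integrin gene Itga7 (13.3 ± 1.44 to 0.56 ± 0.19 TPM) and Tigit. Several fixed genes gave no call. Socs3 was 29 ± 0.96 against 29.1 ± 1.52 TPM, Src 1.04 ± 0.29 against 1.18 ± 0.29 TPM, Lck 422.6 ± 12.5 against 436.3 ± 9.89 TPM and Fyn 151.9 ± 2.1 against 144.3 ± 5.29 TPM. Il17a, Il17f and Il23r lay at or under 0.41 TPM in both Treg groups. Over all genes 2192 were higher and 1285 lower with Srci1 (limma, 133 and 341 at least 2-fold; 63% higher, all-gene median 0.114), against 1369 and 1763 (43.7% higher; 84 and 404 at least 2-fold) under median-of-ratios scaling. The ribosomal protein share was 20.9 ± 0.5% with Srci1 and 25 ± 0.2% with DMSO beside all these groups.

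DMSO-treated Treg cultures differed from DMSO-treated TH17 cultures by lower TH17 program transcripts and higher TH1 program transcripts. All 20 TH17 program genes were lower in Treg cells (relative median -2.43, camera adjusted p = 8.47e-29). Il17a was 0.03 ± 0.05 TPM against 1338 ± 51.5 TPM, Il17f 0.41 ± 0.37 against 2551 ± 111 TPM and Il23r 0.08 ± 0.07 against 7.29 ± 2.86 TPM. Foxp3 was 129.7 ± 2.23 TPM against 11.7 ± 2.15 TPM (limma adjusted p = 9.42e-12). Gzmb was 1279 ± 30.7 TPM in Treg and 6.84 ± 0.29 TPM in TH17 cells, and Nkg7 178.8 ± 9.26 against 2.25 ± 0.45 TPM.

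The TH1 program was higher in 13 of 17 genes, 14 adjusted over the list alone, and lower in 2 (relative median 2.43, camera adjusted p = 2.46e-06). Tbx21 was at 45 ± 1.72 against 0.6 ± 0.13 TPM and Ccl3 at 239.1 ± 4.59 against 13.3 ± 1.98 TPM. Type I interferon genes were higher in 11 of 12 cases (relative median 1.32, camera adjusted p = 2.55e-06), including Irf7 at 15.1 ± 1.11 against 2.42 ± 0.49 TPM and Ifi27l2a at 1864 ± 69.6 against 568.8 ± 70.8 TPM. TCR-induced genes were higher in 17 of 20 cases and lower in 2 (relative median 0.99, camera adjusted p = 2.46e-06; adjusted p = 0.0826 with an estimated correlation). Nr4a3 was 129.9 ± 3.42 against 26 ± 2.29 TPM, Egr3 75.1 ± 2.29 against 19.8 ± 2.37 TPM and Tnfrsf9 1148 ± 19.5 against 395.6 ± 35.2 TPM. The Treg program was higher in 11 of 19 genes and lower in 3 (relative median 0.62, camera adjusted p = 0.00384; adjusted p = 0.159 with an estimated correlation), among them Tigit at 101.7 ± 6.12 against 7.67 ± 0.23 TPM and Izumo1r at 332.9 ± 1.7 against 104 ± 7.04 TPM. Cell cycle genes were higher in 19 of 20 cases (relative median 0.68, camera adjusted p = 1.28e-09; adjusted p = 0.0871 with an estimated correlation). Cdk1 was at 315.6 ± 3.45 against 147.8 ± 12.5 TPM and Aurkb at 136.5 ± 4.73 against 66.9 ± 1.12 TPM.

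CD8 T cell and NK cell markers were higher in 3 and lower in 4 of 8 measured genes (camera adjusted p = 0.418). The T-box factor gene Eomes was 15.3 ± 0.41 against 1.16 ± 0.28 TPM and Prf1 15.8 ± 1.23 against 0.75 ± 0.29 TPM. Klrd1 was 2.87 ± 1.2 against 42.8 ± 1.88 TPM. The other called lists lost the call with an estimated correlation. They were amino acid stress (12 of 15 higher, 1 lower, 12 and 2 adjusted over the list alone, 11 and 3 under median-of-ratios scaling; adjusted p = 0.0826 with an estimated correlation), glycolysis and hypoxia (9 of 18 lower, 14 under median-of-ratios scaling, 2 higher; 0.161), cholesterol synthesis (17 of 20 higher, 18 adjusted over the list alone and 11 under median-of-ratios scaling, 1 lower; 0.254), STAT3 pathway and targets (6 of 15 lower, 4 higher; 0.254) and the TFH program (6 of 10 lower, 2 higher; 0.254). The TGF-beta response (6 of 12 lower, 3 higher, 1 under median-of-ratios scaling; 0.274), Src family kinases and regulators (9 of 12 higher; 0.301) and mitochondrially encoded genes (1 of 13 lower, 0 adjusted over the list alone and 7 under median-of-ratios scaling; 0.333) were the others, and the last call also ended without a filter on low values (camera adjusted p = 0.062) and after quantile normalization (0.74).

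Further large differences were higher Iigp1 (62.9 ± 3.27 against 0.33 ± 0.11 TPM), Ccl1 (54.1 ± 1.91 against 0.2 ± 0.21 TPM) and Ly6c2 (71 ± 7.31 against 0.97 ± 0.63 TPM) in Treg cells. Timp1 (0.54 ± 0.25 against 431.9 ± 36.5 TPM), Il21 (0.94 ± 0.19 against 205.3 ± 35.5 TPM), Ly6g (0.08 ± 0.07 against 88.3 ± 8.1 TPM) and Ltb4r1 (1.25 ± 0.18 against 148.7 ± 7.51 TPM) were lower. Ly6c2 and Ly6g have close copies and are uncertain. Socs3 was 29.1 ± 1.52 against 82.5 ± 5.27 TPM (limma adjusted p = 1.05e-09) and Fyn 144.3 ± 5.29 against 89.7 ± 8.97 TPM (limma adjusted p = 1.52e-06). Stat3, Src and Il2ra gave no call (limma adjusted p = 0.203, 0.549 and 0.55), and Lck, at 436.3 ± 9.89 against 402.1 ± 19.3 TPM, passed at 0.0489 with a direction that turned under median-of-ratios scaling (log2 fold change -0.099). The Lck call ended without DMSO TH17 replicate 1 or 3 (limma adjusted p = 0.0911 and 0.149) or DMSO Treg replicate 1, 2 or 3 (0.146, 0.0593 and 0.11). It also ended after quantile normalization (0.469), after rescaling without ribosomal protein and mitochondrial genes (0.439), with only the compared groups in the fit (0.125) and with array weights (0.122). In all 4132 genes were higher and 1605 lower in Treg cells (limma, 955 and 444 at least 2-fold; 72% higher, all-gene median 0.181), against 2701 and 2789 (49.2% higher; 685 and 590 at least 2-fold) under median-of-ratios scaling.

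The effect of Srci1 differed between the cell types for glycolysis, amino acid stress and TH1 genes, by the interaction contrast. Gzmb rose from 6.84 ± 0.29 to 43.7 ± 2.17 TPM in TH17 cells and fell from 1279 ± 30.7 to 476.6 ± 18.9 TPM in Treg cells, a difference of 3.93 ± 0.09 (SE) on the log2 scale (limma adjusted p = 8.97e-12). Il3 went from 0.84 ± 0.63 to 21.1 ± 4.14 TPM in TH17 cells and from 43.8 ± 3.54 to 13.1 ± 1.39 TPM in Treg cells. Serpina3f, which has close copies and is uncertain, went from 1.64 ± 0.23 to 9.21 ± 0.36 TPM and from 47.3 ± 2.78 to 7.5 ± 0.41 TPM, and Prf1 from 0.75 ± 0.29 to 3.29 ± 0.56 TPM and from 15.8 ± 1.23 to 2.09 ± 0.27 TPM. In the other direction the largest differences by the naming rule were of Il17a, Ly6c1 (uncertain as above), the chemokine receptor gene Ccr2 and Il17f. Their log2 differences were -5.17, -2.91, -2.3 and -2.29. The rule leaves out mitochondrially encoded genes, of which mt-Co3 differed by -4.07. Il17a and Il17f were at or under 0.41 TPM in both Treg groups.

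An effect is called higher where its log2 fold change is higher, so a smaller fall counts as higher too. All 18 glycolysis and hypoxia genes had a higher Srci1 effect in TH17 than in Treg cells (relative median 0.53, camera adjusted p = 3.53e-15), 11 of them under median-of-ratios scaling. The list fell in both cell types (relative median -0.46 in TH17 and -1.08 in Treg cells), so this was a smaller fall in TH17 cells. Slc16a3 went from 340.1 ± 53.5 to 236.4 ± 16.2 TPM in TH17 cells and from 333.1 ± 18 to 75.2 ± 5.25 TPM in Treg cells. Amino acid stress genes had a higher effect in TH17 cells in 13 of 15 cases, 14 adjusted over the list alone (relative median 0.7, camera adjusted p = 2.55e-13). Asns was 42.6 ± 5.44 and 53.1 ± 2.43 TPM in TH17 cells with DMSO and Srci1, and 83.8 ± 2.3 and 24.7 ± 3.86 TPM in Treg cells. The same direction held for 10 of 17 TH1 genes, 11 adjusted over the list alone, with 1 opposite (camera adjusted p = 6.51e-06). It held for 10 of 12 type I interferon genes and 10 of 15 STAT3 pathway and targets genes, each with 0 opposite (camera adjusted p = 6.51e-06 for both lists). Tbx21 of the TH1 list lay at 0.48 to 0.73 TPM with DMSO and 0.49 to 0.74 TPM with Srci1 in TH17 cells. A fall could hardly show there, so its difference rests on the fall in Treg cells. Il12rb2 of that list, at 18.89 to 35.26 TPM with DMSO in TH17 cells, was not near 0. The Socs3 effect differed by 0.91 ± 0.1 (SE; limma adjusted p = 4.29e-05). Stat3 differed by 1.19 and Foxp3 by 2.98 on the log2 scale (limma adjusted p = 9.83e-05 and 2.13e-08). Src differed by 0.86 (limma adjusted p = 0.0246), a call that ended after quantile normalization (0.0681) and without DMSO TH17 replicate 3 (0.0528), Srci1 TH17 replicate 2 or 3 (0.0565 and 0.0591), DMSO Treg replicate 2 or 3 (0.0617 and 0.0607) or Srci1 Treg replicate 3 (0.0617). Lck, Fyn, Il23r and Il2ra gave no call (limma adjusted p = 0.646, 0.536, 0.224 and 0.267), though Il23r gave one without DMSO TH17 replicate 3 (0.0222), after quantile normalization (0.0268) and with array weights (0.0346).

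Cholesterol synthesis (16 of 20 higher, 18 adjusted over the list alone), the TH2 program (7 of 10, 8 adjusted over the list alone) and the Treg program (9 of 19, 10 adjusted over the list alone) had higher effects in TH17 cells with 0 members opposite (camera adjusted p = 3.06e-10, 2.05e-06 and 6.51e-06). The TH17 program had lower effects in 8 and higher effects in 4 of 20 genes (camera adjusted p = 2.39e-05; adjusted p = 0.053 with an estimated correlation). The cell cycle (12 of 20 higher, 7 under median-of-ratios scaling), p53 response (4 of 9 higher) and mitochondrially encoded (3 of 13 lower, 5 under median-of-ratios scaling) lists were called too, with adjusted p = 0.147, 0.128 and 0.0751 with an estimated correlation. The TH17 program call also ended with a pseudocount of 0.1 (camera adjusted p = 0.0546). Over all genes 1443 effects were higher and 378 lower in TH17 cells (limma, 79.2% higher, all-gene median 0.127), against 1137 and 710 (61.6% higher) under median-of-ratios scaling. Of 100 relabellings of DMSO and Srci1 libraries within each cell type, the real one included, 5 called at least as many genes, and the other 4 kept the TH17 libraries divided as they were, with the labels exchanged.

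In a direct test of Srci1-treated against knockout TH17 libraries, Foxp3 gave no call, while STAT3 targets, TH17, glycolysis and cholesterol synthesis genes were higher with Srci1. Srci1 was added 24 h after plating at an unknown dose, whereas the knockout cells came from mice lacking STAT3 in T cells. Timing, dose and genotype thus cannot be told apart in these differences. Foxp3 was 203.6 ± 8.37 TPM with Srci1 and 204.6 ± 17.6 TPM in the knockout (limma adjusted p = 0.974; 0.0442 after quantile normalization). Socs3 was 154.8 ± 3.58 against 10.2 ± 0.55 TPM, Pim1 548.7 ± 15.5 against 65.3 ± 2.1 TPM and Il2ra 1208 ± 70.7 against 371.8 ± 46.8 TPM, all higher with Srci1 (limma adjusted p = 2.06e-13, 2.98e-13 and 8.85e-09). Il17f was 531.4 ± 18.1 against 19.1 ± 0.75 TPM and Il17a 40.4 ± 3.31 against 10.2 ± 1.45 TPM.

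Of 15 STAT3 pathway and targets genes, a list that includes the deleted Stat3, 12 were higher with Srci1 and 1 lower, 13 and 1 adjusted over the list alone (relative median 1.43, camera adjusted p = 9.76e-07). The TH17 program was higher in 18 and lower in 2 of 20 genes (relative median 1.64, camera adjusted p = 7.22e-08). Ltb4r1 was at 48.8 ± 2.59 against 0.1 ± 0.09 TPM and Il24 at 20.2 ± 3.2 against 0.05 ± 0.05 TPM. All 20 cholesterol synthesis genes (relative median 1.22, camera adjusted p = 2.25e-12) and all 18 glycolysis and hypoxia genes (relative median 1.37, camera adjusted p = 1.65e-15) were higher with Srci1. Fdps was 498 ± 5.16 against 108.7 ± 13.8 TPM and Egln3 162.8 ± 0.77 against 10.1 ± 1.11 TPM. The IL-2 and STAT5 response was higher in 11 of 12 genes (camera adjusted p = 3.34e-07), including Cish at 209.5 ± 6.58 against 64.3 ± 3.25 TPM and Gzmb at 43.7 ± 2.17 against 6.85 ± 0.48 TPM. The TH2 program (9 of 10 higher, 1 lower), amino acid stress (13 of 15 higher, 1 lower, 13 and 2 adjusted over the list alone) and unfolded protein response (11 of 12 higher) lists were called in the same direction (camera adjusted p = 0.00218, 0.0001 and 9.51e-06).

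The TH1 program was lower with Srci1 than in the knockout in 10 of 17 genes and higher in 5 (relative median -1.24, camera adjusted p = 0.0063; after quantile normalization 0.0502). Ccl4 was at 10.5 ± 0.96 against 230 ± 18.6 TPM, Tbx21 at 0.6 ± 0.13 against 21.9 ± 2.71 TPM and Nkg7 at 3.52 ± 1.34 against 551.2 ± 37.2 TPM. TCR-induced genes were lower in 12 of 20 cases and higher in 4, 13 and 4 adjusted over the list alone (relative median -1, camera adjusted p = 0.000465; adjusted p = 0.115 with an estimated correlation). Egr3 was at 5.62 ± 0.39 against 36.8 ± 3.96 TPM and Egr2 at 5.71 ± 1.35 against 32.6 ± 4.01 TPM. Type I interferon genes (8 of 12), B cell markers (5 of 6, with 1 higher) and myeloid and dendritic cell markers (5 of 6, with 1 higher) were lower with Srci1 (camera adjusted p = 0.000305, 0.0035 and 0.00407). The TGF-beta response was lower in 6 of 12 and higher in 2 genes (camera adjusted p = 0.0157; adjusted p = 0.271 with an estimated correlation).

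The largest differences toward Srci1 were of Ubd (217.1 ± 9.44 against 1.2 ± 0.73 TPM), the fatty acid desaturase gene Scd1 (132.2 ± 15.9 against 0.65 ± 0.2 TPM), AA467197 (144.3 ± 2.1 against 0.96 ± 0.74 TPM) and Upp1 (186.7 ± 13.5 against 1.45 ± 0.42 TPM). Toward the knockout they were of Nkg7, Xcl1 (16.7 ± 3.99 against 1584 ± 69.7 TPM), Lcn10 (0.03 ± 0.05 against 72.2 ± 5.54 TPM) and Ccl1 (2.4 ± 0.65 against 135.2 ± 4.35 TPM). Lck and Fyn were lower with Srci1 than in the knockout (limma adjusted p = 2.39e-05 and 8.6e-05), Il23r was higher (3.26e-06), and Src was 2.37 ± 0.31 against 3.63 ± 0.27 TPM with a limma adjusted p of 0.0326. The Src call ended without STAT3 knockout replicate 1 or 3 (limma adjusted p = 0.0947 and 0.0643) or Srci1 TH17 replicate 1 or 3 (0.114 and 0.0512), with a pseudocount of 0.1 (0.096) and without a filter on low values (0.0562). In all 3922 genes were higher and 2361 lower with Srci1 (limma, 62.4% higher, all-gene median 0.114), against 3147 and 3130 (50.1% higher) under median-of-ratios scaling.

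**Figure D3:**
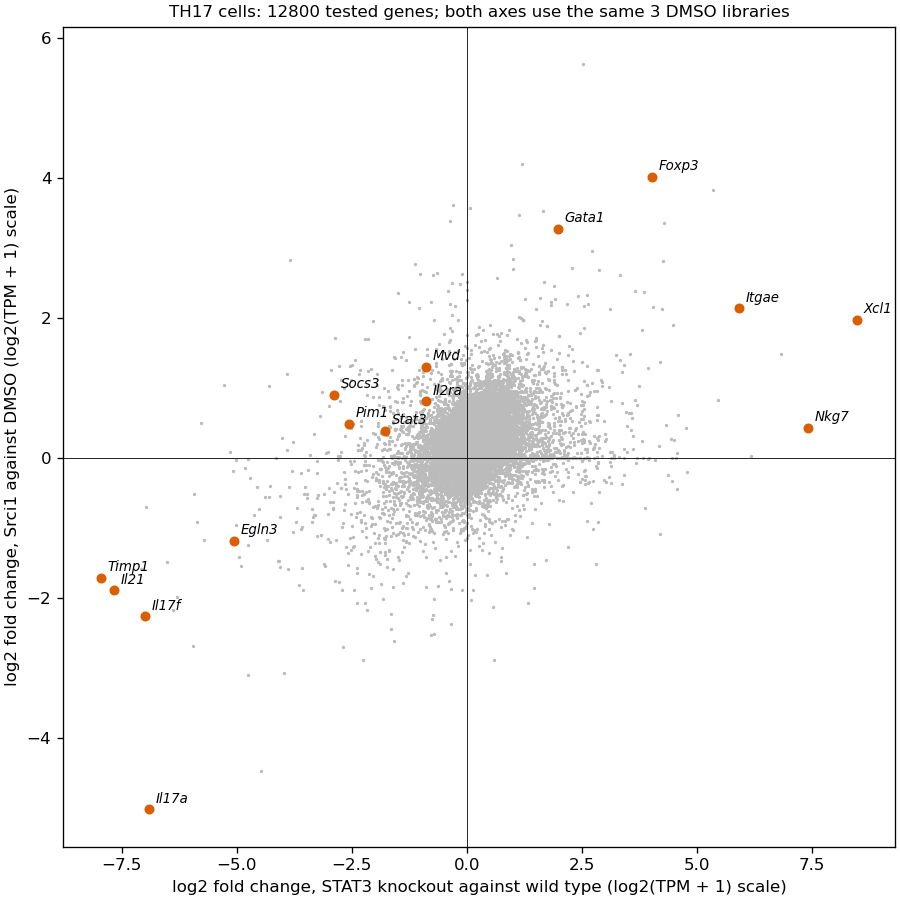
Log2 fold change of TPM + 1 for Srci1 against DMSO (vertical) and for STAT3 knockout against wild type (horizontal) in TH17 cells, with a grey point per tested gene and named genes in orange. Both axes use the same 3 DMSO libraries. Foxp3 lies at 4.02 and 4.03, Il17a at -5.02 and -6.91, and Socs3 at 0.9 and -2.89.

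Both comparisons in TH17 cells called 2032 genes higher and 536 lower. Independent lists of those sizes would share 1335 and 170.9 genes. Another 500 genes were higher with Srci1 and lower in the knockout, against 815.5 for independent lists, and 119 were lower with Srci1 and higher in the knockout, against 279.7. Foxp3 and Itgae were higher and Il17a, Il17f, Il21 and Egln3 lower in both, while Socs3, Pim1, Il2ra and Mvd rose with Srci1 and fell in the knockout. In 100 simulations of unchanged groups, in which the DMSO libraries were redrawn as well, the median overlap was 0 in every direction. Without simulated effects almost no gene is called, so that overlap does not show how much the shared DMSO libraries add. The correlation of fold changes across genes, which are not independent replicates, was r = 0.371 against a simulated 0.4945, and the covariance 0.1656 against a simulated 0.02488, a difference of 0.1407. The 3 shared DMSO libraries cannot be split into parts of at least 2, so part of the excess overlap may come from them. Median-of-ratios scaling gave 1121 genes higher in both, 1172 lower in both, and 297 and 234 in the opposite directions.

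**Figure D4:**
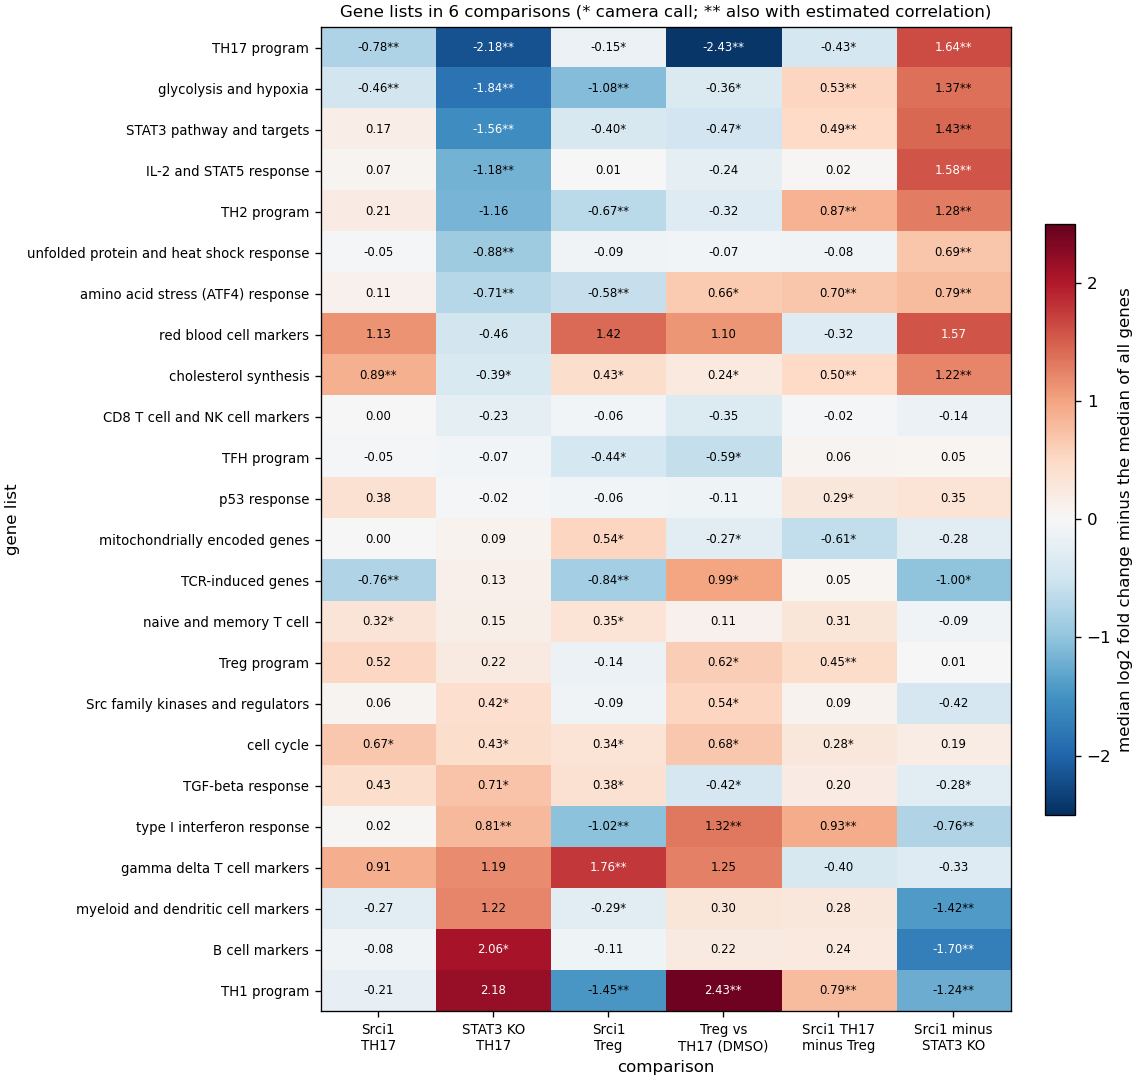
Median log2 fold change of each of the 24 gene lists (down the side) in the 6 comparisons (across), minus the median of all genes, with red above and blue below 0. A single asterisk marks a camera call and a double asterisk a call that also held with an estimated correlation. Glycolysis and hypoxia genes lay at -0.46, -1.84 and -1.08 in the comparisons of Srci1 in TH17 cells, STAT3 knockout and Srci1 in Treg cells.

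Several lists without a call had a median, mean and camera direction of different sign. With Srci1 in TH17 cells these were the TH1, TFH, type I interferon, unfolded protein, mitochondrially encoded and CD8 and NK lists. They were the TFH and p53 lists in the knockout, and the Src family, p53, unfolded protein and CD8 and NK lists with Srci1 in Treg cells. Between Treg and TH17 cells they were the naive and memory, IL-2 and STAT5, p53, unfolded protein and CD8 and NK lists. In the interaction they were the TFH and TGF-beta lists, and between Srci1 and knockout the Treg, TFH and CD8 and NK lists. Further lists called in the STAT3 knockout against wild type were the cell cycle (18 of 20 rose; adjusted p = 0.159 with an estimated correlation), the TGF-beta response (10 of 12 rose, 1 fell; 0.159) and Src family kinases and regulators (9 of 12 rose, 1 fell; 0.44). The last of these lost its call with a stricter filter (camera adjusted p = 0.0581) or without DMSO TH17 replicate 3 (0.0562).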

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

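All tests of explanations in this part were chosen after the results were seen. The results collected here are those for which the Srci1 effect differed between TH17 and Treg cells by the interaction contrast in limma. Groups of 3 libraries are too small for a test of single outlying libraries.

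The Srci1 effect, signed so that a smaller fall counts as higher, was higher in TH17 than in Treg cells for 1443 genes and lower for 378. The largest higher effects by the naming rule had log2 differences of 5.29 (Il3), 4.46 (Serpina3f), 3.93 (Gzmb) and 3.74 (Prf1). The TH1 genes Tbx21, Il12rb2 and Ccl5 had differences of 1.85, 2.21 and 2.02. Tbx21 lay at or under 0.74 TPM in both TH17 groups, where a fall could hardly show. The CD8 T and NK cell list, with 3 of 8 genes higher and 1 lower, was not called (camera adjusted p = 0.633). Glycolysis and stress genes differed by 2.06 (Egln3), 1.62 (Slc16a3), 0.78 (Aldoa), 1.04 (Bnip3), 2.05 (Asns), 1.05 (Ddit4), 1.87 (Trib3) and 0.83 (Cars). Of these, Egln3, Slc16a3, Aldoa and Bnip3 were lower with Srci1 in both cell types, by less in TH17 cells. The fixed genes Stat3, Src, Foxp3 and Socs3 differed by 1.19, 0.86, 2.98 and 0.91, and Fos and Fosl2 by 1.68 and 1.83. Lower effects in TH17 cells were those of Il17a (-5.17), Ly6c1 (-2.91), Ccr2 (-2.3) and Il17f (-2.29), of which Il17a and Il17f were at or under 0.41 TPM in both Treg groups.

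Among the lists, the median difference, here not relative to the all-gene median of 0.127, was 1.06 for the type I interferon response, 0.99 for the TH2 program, 0.91 for the TH1 program, 0.83 for amino acid stress, 0.66 for glycolysis and hypoxia, 0.62 for cholesterol synthesis, 0.62 for STAT3 pathway and targets and 0.58 for the Treg program. It was 0.42 for the p53 response, 0.4 for the cell cycle, -0.31 for the TH17 program and -0.48 for mitochondrially encoded genes, 4 lists whose calls ended with an estimated correlation. Of 100 relabellings of DMSO and Srci1 libraries within each cell type, 5 gave as many as the 1821 calls, the real one included, and the highest other gave 1926. The other 4, with 1926, 1900, 1893 and 1837 calls, exchanged all 3 TH17 libraries of each group and 1 Treg library of each group. They thus kept the division of the TH17 libraries with its sign turned and hold that effect, so this count does not decide whether chance can be excluded.

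With Srci1 in TH17 cells 82.7% of calls were higher, a pattern that differs from an even split of directions. After rescaling without ribosomal protein and mitochondrial genes the share was 71% (67 to 73.4% with a library left out), which argues against the lower ribosomal protein share as the whole cause. Without DMSO TH17 replicate 3 it was 79.2%, against 81.6 to 84.5% without another library, which argues against that library as the whole cause. A change of total RNA output stays open and cannot be told apart, since median-of-ratios scaling gave 50.2% by its own centring and TPM holds no total.

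The knockout libraries kept 28.34% of the wild-type Stat3 level (25.45 to 31.82% per library). If a share of cells had kept Stat3 and expressed every gene as wild-type cells do, no abundant gene would lie far under that share. Of 5079 genes with at least 20 TPM in wild type, 69 lay under 50% of the Stat3 ratio in every knockout library, among them Il17a at 0.76% and Il17f at 0.75%, which argues against that explanation. Transcript from exons outside the deleted part remains open, because a gene-level table does not show exons.

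Xcl1 and Nkg7 rose strongly in the STAT3 knockout, and cells of another type in these cultures may be a candidate source. Of the NK cell transcripts, Klrd1 fell (log2 fold change -4.29) and Klre1 was listed at 0 in every knockout library. Klrd1 held 42.8 ± 1.88 TPM in wild-type cultures, so its fall alone could not exclude added NK cells. The level left in the knockout, 1.27 ± 0.5 TPM, argues only against many NK cells that express Klrd1 and Klre1. Of the CD8 T and NK cell list, 3 of 8 measured genes rose and 3 fell. CD8 T cells stay open, since Cd8b1, chosen after its values were seen, was 8.66 ± 1.39 TPM against 7.23 ± 0.6 TPM (log2 fold change 0.22, limma adjusted p = 0.235) while Cd8a rose from 0.02 ± 0.03 to 4.74 ± 0.59 TPM. Cd4, also chosen after its values were seen, was 209.8 ± 13.1 against 275.7 ± 52.9 TPM, and the sort was for CD4 cells. A change within the CD4 T cells that lack STAT3 is the biological explanation the design names, and it was not tested apart from these.

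For each comparison of 3 against 3 libraries only 10 splits exist, too few for a share under 0.05. The real split gave 5230 calls for Srci1 in TH17 cells (highest other 1), 6366 for the knockout (144), 3477 for Srci1 in Treg cells (1), 5737 for Treg against TH17 cells (1) and 6283 for Srci1 against knockout (1).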

How the results depend on the processing

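The rescaling without ribosomal protein and mitochondrial genes, the list tests without DMSO TH17 replicate 3, and the limit of list directions to called or described lists were chosen after the data were seen. Of 278 results of genes chosen by the naming rule, 260 kept direction and side of the threshold in every alternative, and of the 259 called, 2 (Fyn with Srci1 in TH17 cells and Lck between Treg and TH17 cells) reversed and 6 lost the call in some alternative. Of 83 list results 42 kept both, and no called list reversed. Median-of-ratios scaling, quantile normalization and only the compared groups gave 2126, 2159 and 2859 genes higher with Srci1 in TH17 cells, and the first 2 gave 2112 and 1973 lower. With Srci1 in Treg cells 1369 genes were higher under median-of-ratios scaling and 3452 with array weights. Median-of-ratios scaling and quantile normalization gave 2701 and 2710 genes higher and 2789 and 2739 lower in Treg than TH17 cells, and 710 and 827 lower Srci1 effects in TH17 than in Treg cells. The same scalings gave 1121 and 1109 genes higher and 1172 and 1095 lower in both Srci1 and knockout, 297 and 316 higher with Srci1 and lower in the knockout (322 with the added rescaling), and 234 and 259 the other way (191). Genes at least 2-fold higher and lower with Srci1 in TH17 cells numbered 250 and 289 after quantile normalization and 874 and 281 with a pseudocount of 0.1 (552 and 164 as reported), and 261 were higher in Treg cells with that pseudocount (133). In the interaction 312 were at least 2-fold higher and 171 lower after quantile normalization (477 and 108), and 68 lower with the stricter filter. Both scalings centre the genes, which moves calls from higher to lower by construction, and the cause was not tested for the other settings. Lists called numbered 10 without a filter for Srci1 in TH17 cells (6 as reported), and with an estimated correlation 7 for the knockout (12), 7 for Srci1 in Treg cells (16) and 3 for Treg against TH17 cells (14).

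Reversed log2 values follow, and the cause was not tested. Under median-of-ratios scaling they were Lck -0.263 and Fyn -0.095 with Srci1 in TH17 cells, Fyn -0.049 and Il17f -0.004 with Srci1 in Treg cells, Stat3 -0.053, Lck -0.099 and Il2ra -0.135 between Treg and TH17 cells, and Lck -0.093 and Fyn -0.045 in the interaction. Under quantile normalization they were Lck -0.125 and Fyn -0.030 with Srci1 in TH17 cells and Lck -0.003 and Fyn -0.046 in the interaction. Under the added rescaling Lck was -0.105 with Srci1 in TH17 cells and -0.004 in the interaction, and with array weights Lck was -0.020 with Srci1 in TH17 cells and Foxp3 0.042 between Srci1 and knockout. Leaving out a library reversed uncalled values within ranges of -0.024 to 0.044 for Lck with Srci1 in TH17 cells (lower than 0 without DMSO TH17 replicate 3 and, at -0.008, Srci1 TH17 replicate 2), -0.049 to 0.179 for Il2ra between Treg and TH17 cells (lowest without DMSO TH17 replicate 3) and -0.049 to 0.064 for Foxp3 between Srci1 and knockout (above 0 without knockout replicate 2 and, at 0.030, Srci1 TH17 replicate 1). With Srci1 in Treg cells the ranges were -0.214 to 0.022 for Src (highest without Srci1 Treg replicate 3), -0.107 to 0.234 for Il17f (below 0 without DMSO Treg replicate 2 and, at -0.041 and -0.052, DMSO and Srci1 Treg replicate 1) and -0.047 to 0.023 for Socs3 (above 0 without DMSO Treg replicate 3 and, at 0.009 and 0.018, DMSO and Srci1 Treg replicate 1). With the stricter filter the CD8 T and NK cell list had a median of 0.43 in the knockout and 1.15 between Treg and TH17 cells.

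With a library left out, genes higher and lower ranged from 3290 to 4646 and 742 to 866 for Srci1 in TH17 cells, 3330 to 4087 and 2083 to 2698 for the knockout, 1510 to 1716 and 1047 to 1103 for Srci1 in Treg cells, 3346 to 4476 and 1352 to 1656 for Treg against TH17 cells, 1048 to 1722 and 257 to 394 for the interaction, and 3300 to 4088 and 2060 to 2246 for Srci1 against knockout. The calls in both Srci1 and knockout ranged from 1529 to 2274 higher and 432 to 533 lower, and those in opposite directions from 397 to 473 and 87 to 101. Without DMSO TH17 replicate 3 the lists called numbered 6 for Srci1 in TH17 cells, 11 for the knockout, 15 for Treg against TH17 cells and 12 for the interaction. None of these counts moved by more than 1.5 times. Deviations of same-numbered libraries correlated at -0.17 to 0.13, and 2 of 30 pairs lay above 0.1. Of 15 libraries, 3 correlated best with their own number. These values gave no sign that the replicate numbers pair the libraries, but 3 libraries per group cannot exclude a shared source. With the replicate block, genes higher and lower were 4186 and 877, 3898 and 2382, 2056 and 1230, 4043 and 1556, 1326 and 329, and 3873 and 2307 in the same order, and of the named genes' calls only Fyn with Srci1 in TH17 cells (limma adjusted p = 0.0603) and Lck between Treg and TH17 cells (0.0563) were lost. TPM holds no depth, so what depth limits cannot be given.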

Other observations

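All tests in this part, and the gene families, were chosen after the data were seen. All 10 measured guanylate-binding protein genes, which encode interferon-induced GTPases, were higher in the STAT3 knockout than in wild type and higher in Treg than in TH17 cells, also under median-of-ratios scaling (camera adjusted p = 5.31e-07 and 2.13e-07; adjusted p = 0.174 and 0.178 with an estimated correlation). Of the same 10, 9 were lower with Srci1 than in the knockout and 0 higher (camera adjusted p = 1.21e-08; adjusted p = 0.106 with an estimated correlation). Killer cell lectin-like receptor genes went the other way. Of 9 measured, 6 were lower and 0 higher in the knockout, 7 lower and 1 higher in Treg than in TH17 cells, and 8 higher and 0 lower with Srci1 than in the knockout (camera adjusted p = 0.0148, 0.0108 and 0.023 with an estimated correlation). These receptor genes have close copies, so reads may be shared between them, and the log2 fold change of Klrd1 in the knockout was -4.29.

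Ribosomal protein genes fell in 60 of 88 cases with Srci1 in TH17 cells and rose in 3 (relative median -0.5, camera adjusted p = 1.78e-35; adjusted p = 0.0343 with an estimated correlation). Under median-of-ratios scaling 73 fell and 1 rose. In Treg cells 53 fell and 2 rose (49 and 2 under median-of-ratios scaling; adjusted p = 0.213 with an estimated correlation), and in the knockout 15 rose and 10 fell, a direction that turned to 1 and 15 under median-of-ratios scaling. Cytosolic tRNA synthetase genes, several of which are ATF4 targets, fell in 13 of 17 cases in the knockout and rose in 1, and 14 of 17 were higher and 0 lower with Srci1 than in the knockout (adjusted p = 0.174 and 0.106 with an estimated correlation). Under median-of-ratios scaling these counts were 13 and 1, and 14 and 1. Histone genes were higher in 27 of 56 cases in Treg than in TH17 cells and lower in 0 (21 and 1 under median-of-ratios scaling; adjusted p = 0.178 with an estimated correlation).

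A first hypothesis was that Srci1 lowers STAT3 target transcripts as the knockout does. The STAT3 pathway and targets list had a median log2 difference of 1.55 between Srci1 and knockout (camera adjusted p = 0.0221 with an estimated correlation) and a median of 0.39 with Srci1 against DMSO, or 1.43 and 0.17 relative to the median of all genes. The list was not called with Srci1 against DMSO (camera adjusted p = 0.575). The difference argues against a fall as in the knockout for this list as a whole. Some members did fall, since with Srci1 against DMSO 2 of 15 fell and 7 rose, 5 each under median-of-ratios scaling. Il17a, Il17f and Il21, which fell both with Srci1 and in the knockout, stand outside this list, so the test does not cover them. The list includes Stat3, which is deleted in the knockout, and transcript levels do not measure STAT3 phosphorylation. Srci1 was added only 24 h after plating and at an unknown dose, so a difference from the knockout may also come from timing or dose.

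Another hypothesis was that Srci1 moves TH17 cells toward the profile of the Treg cultures. Of 955 genes at least 2-fold higher in Treg than in TH17 cells, 494 rose and 64 fell with Srci1, and of 444 at least 2-fold lower, 187 fell and 75 rose, where 82.7% of all Srci1 calls were higher (259 and 90 of 685, and 299 and 60 of 590, under median-of-ratios scaling). In the knockout 680 of the 955 rose and 47 fell, and 363 of the 444 fell and 26 rose, against 479 and 48 of 685, and 472 and 34 of 590, under that scaling. The covariance of the fold changes exceeded that of simulated unchanged groups by 0.1335 for Srci1 and 0.3815 for the knockout. Under median-of-ratios scaling the excess was 0.144 and 0.4016. Such an excess is what the hypothesis predicts, but lists went both ways. Relative medians are given for Treg against TH17 cells and then for Srci1 in TH17 cells. The TH17 program (-2.43 and -0.78), cell cycle (0.68 and 0.67), cholesterol synthesis (0.24 and 0.89) and glycolysis and hypoxia (-0.36 and -0.46) shared a direction. TCR-induced genes did not (0.99 and -0.76). The TH1 program (2.43 and -0.21) and the Treg program (0.62 and 0.52) were not called with Srci1. The simulation redrew the DMSO libraries too, from a spread pooled over the groups, so a wider spread of the real DMSO libraries is not covered. The genes counted above were chosen with the DMSO TH17 libraries that the other fold changes also use, which favours these directions. The correlations across genes, which are not independent replicates, were 0.421 and 0.618 against a simulated 0.5, and the excess covariance may hold processes shared by any departure from the TH17 state, which this test does not separate.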
